A study of Coprinopsis cinerea AmutBmut pab1-1 with 201 samples.

How the data were processed

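RNA was measured in Coprinopsis cinerea AmutBmut pab1-1, an inky cap mushroom strain with mutations in both mating type factors that forms fruiting bodies without a partner. The 201 libraries belonged to 67 groups of 3, covering germinating oidia (asexual spores) and basidiospores (sexual spores), mycelium grown in the dark, its response to light, hyphal knots (the earliest aggregates of a fruiting body), primordia, sclerotia, starvation and a panel of stresses. Per the labels' protocols, RNA was isolated with a column kit and made into QuantSeq 3′ mRNA libraries, in which an oligo-dT primer starts the first strand and a random primer the second. Such reads lie close to the 3′ end of a transcript, so the counts need no correction for transcript length, but a gene whose annotated end is wrong loses its reads. Single-end reads of 75 bp were sequenced on a NextSeq instrument. Groups and replicate numbers were taken from the sample titles. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

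The authors deposited 1 table of expected counts per gene that are not normalized, together with their CopciAB V2 gene annotation. Per the submitters' processing notes, STAR 2.6.1a and featureCounts were used. The version of featureCounts, the strand setting and the treatment of reads with several hits are not given in the sources used here. Of the nonzero deposited counts, 19.9% were not whole numbers (tolerance 0), which happens when a read with several hits is split among them, so genes with close copies hold shared reads. In 43 groups of gene models, 100 models together, the counts were identical in every library, and 8 of these models had 1000 or more counts in all. A further measure of sharing was the share of libraries in which a gene had a value that was not whole. It reached 50% or more of the libraries with a count for 1563 models. The table held 13617 genes, each matched to 1 transcript model of the annotation, whose 14750 models on 20 scaffolds included 1133 isoforms that were not counted. Among the counted genes, 3487 overlapped another one on the other strand and 575 on the same strand, and their counts are uncertain. A 3′ UTR was annotated for 12130 genes, with a median length of 142 bp, and 25 genes had no count in any library. The deposited counts were rounded to whole numbers before fitting. No column of per-sample values was left out.

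Total counts per library ranged from 213736 to 26101402 with a median of 9984538, and 192 of the 201 libraries held 5290494 or more. With 3 counts taken as the floor over a group of libraries, a gene at 0 in a group was given only a lower bound of its fold. Reads without molecular identifiers are not independent molecules, so floors cover counting error only. No pair of libraries within a group was identical. The lowest chi-square per degree of freedom among the 201 pairs of libraries of 1 group was 2.39, above sampling noise, so every library was kept as its own replicate. Over 10576 genes, the median correlation of a library with its own group was 0.967, and 32 libraries were closer on average to another group than to their own.

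Groups that share a control or a time course were fitted together, in 12 fits. Each fit used edgeR 4.0.16 in R 4.3.3 with TMM scaling, the filterByExpr filter at a minimum count of 10 and the robust quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of 2 or more. There were 44 comparisons between groups and 2 tests of whether the response to light differed between aerial and attached mycelium. Counts were scaled to a common library size as CPM, and log2 CPM were computed with a prior count of 2. Simulated data were drawn from the means of the control, used for every library of a fit, and from the real library sizes. In them 200 genes were changed, 50 for each size of fold. The heat shock comparison recovered 24% of 2-fold, 86% of 4-fold, 98% of 8-fold and 98% of 16-fold changes among 10578 genes, with 4 false calls. The comparison of Trichoderma overgrowth recovered 34% of 2-fold and 76% of 4-fold changes among 9580 genes, with 13 false calls. There 3 gene models that took 41.7% of the real overgrown counts on average kept their control share in the simulation. The recovery for overgrowth may therefore be overstated. The hypoxia comparison recovered 24% of 2-fold and 82% of 4-fold changes among 10100 genes, with 15 false calls, and the copper comparison 10% of 2-fold and 64% of 4-fold changes among 10195 genes, with 5 false calls.

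Of the 13617 gene identifiers, 0 matched the reference table of 13657 genes, and the deposited files do not pair them with names or products. The 34 lists by product name that had been written for this study, such as heat shock proteins or hydrophobins, could therefore not be applied. Groups of genes were described by 14 response sets instead, each made of the 100 genes with the largest fold among those called higher in 1 group than in another, with every library of the former above every library of the latter and a mean of 10 CPM or more. Only 75 genes qualified for the copper set and 58 for the hypoxia set. The oidium and spore sets are genes higher in ungerminated oidia and in ungerminated basidiospores than in 36 h mycelium, and the young mycelium set compares 12 h with 132 h in the dark. The aerial set compares aerial with attached mycelium at 156 h in the dark, the light set 1 h of light with darkness in aerial mycelium, the hyphal knot set knots with attached mycelium 24 h after light, and the primordium set 24 h primordia with knots. Primordia is the name used here for samples from 6 to 24 h of a cycle of 12 h light and 12 h dark. Their titles name no tissue, so stage and renewed light were not separated. The starvation set compares 24 h on water agar with 60 h mycelium, and the heat, peroxide, copper, hypoxia, Trichoderma (first contact) and sclerotium sets compare each condition with its control. The sets are made from the study's own samples, so each was tested only in comparisons that share no library with its definition. They are not disjoint, the largest overlap being 19 genes between the spore and sclerotium sets. Genes near 0 in a control passed the count filter only through other groups of the fit, which favours rises over falls there. Sets were tested with camera from limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over all 554 pairs of a set and a comparison. The median change of a set is given as log2, and its course over time as the mean over libraries of the library medians, relative to the starting group.

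Overlaps of calls were tested with Fisher's exact test in comparisons that share no library. Genes changed in most stresses, a name for those called one way in at least 5 control sets, were counted over 19 comparisons in 8 control sets. Sclerotia were counted among the stresses. The numbers were set against 1000 shuffles of genes within each control set. Neighbouring genes called in the same direction were counted along the scaffolds and set against 1000 shuffles of the calls, and the longest unbroken run of called neighbours against 200 shuffles. Alternatives were RLE scaling factors, DESeq2 1.42.0, no filter, a replicate block, a fit of the compared groups alone, a fit of all 67 groups, leaving out each library in turn, sets of 50 or 200 genes and other minimum numbers of control sets. These tests, the alternatives, the set definitions and the rule for naming genes were fixed before the data were examined. The rule took, for 13 lead comparisons, at most the 2 higher and 2 lower genes with the largest fold among called genes whose libraries did not overlap between groups and whose higher group had a mean of 10 CPM or more, a separation that chance gives for 10% of genes. The text names fewer, in that order, passing over genes whose lower group held above 0 and at most 3 counts. Coordinates are those of the CopciAB V2 annotation.

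Same-numbered libraries were checked for pairing by the correlation of their deviations from the group means. In 1 of the 44 comparisons, aerial mycelium at 24 h after light, every pair correlated above 0.1 (0.106 to 0.261), and there the numbers were taken to pair the samples. The reported counts and set tests of that comparison still come from the fit without pairing. The pairing entered only through the replicate block, an alternative for the counts. The titles give the numbers, and nothing in the labels says what they mark. No genome sequence was used here, so GC content was not analysed.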

Results

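Transcripts of 13617 genes of Coprinopsis cinerea were counted in 201 libraries, 3 for each of 67 groups that follow the fungus from germination through vegetative growth, light induction and the start of fruiting, and through starvation, sclerotia and stress. Total counts per library ranged from 213736 to 26101402, with a median of 9984538. The lowest totals, 213736, 533936 and 961041, belonged to the mycelium overgrown by Trichoderma. Next came library 1 of attached mycelium 12 h after light with 1034515 and library 1 of the cold treatment with 1673596. Genes had identifiers but no names, so groups of genes are described by response sets, genes that define a condition in 1 part of the series and were then followed in parts that share no library with it. Camera with its preset correlation called 247 of 554 pairs of a set and a comparison, and 18 of these calls held with an estimated correlation. Those 18 are the ones given below with an adjusted p under 0.05 with an estimated correlation, and the others rest on the preset value.

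**Figure D1:**
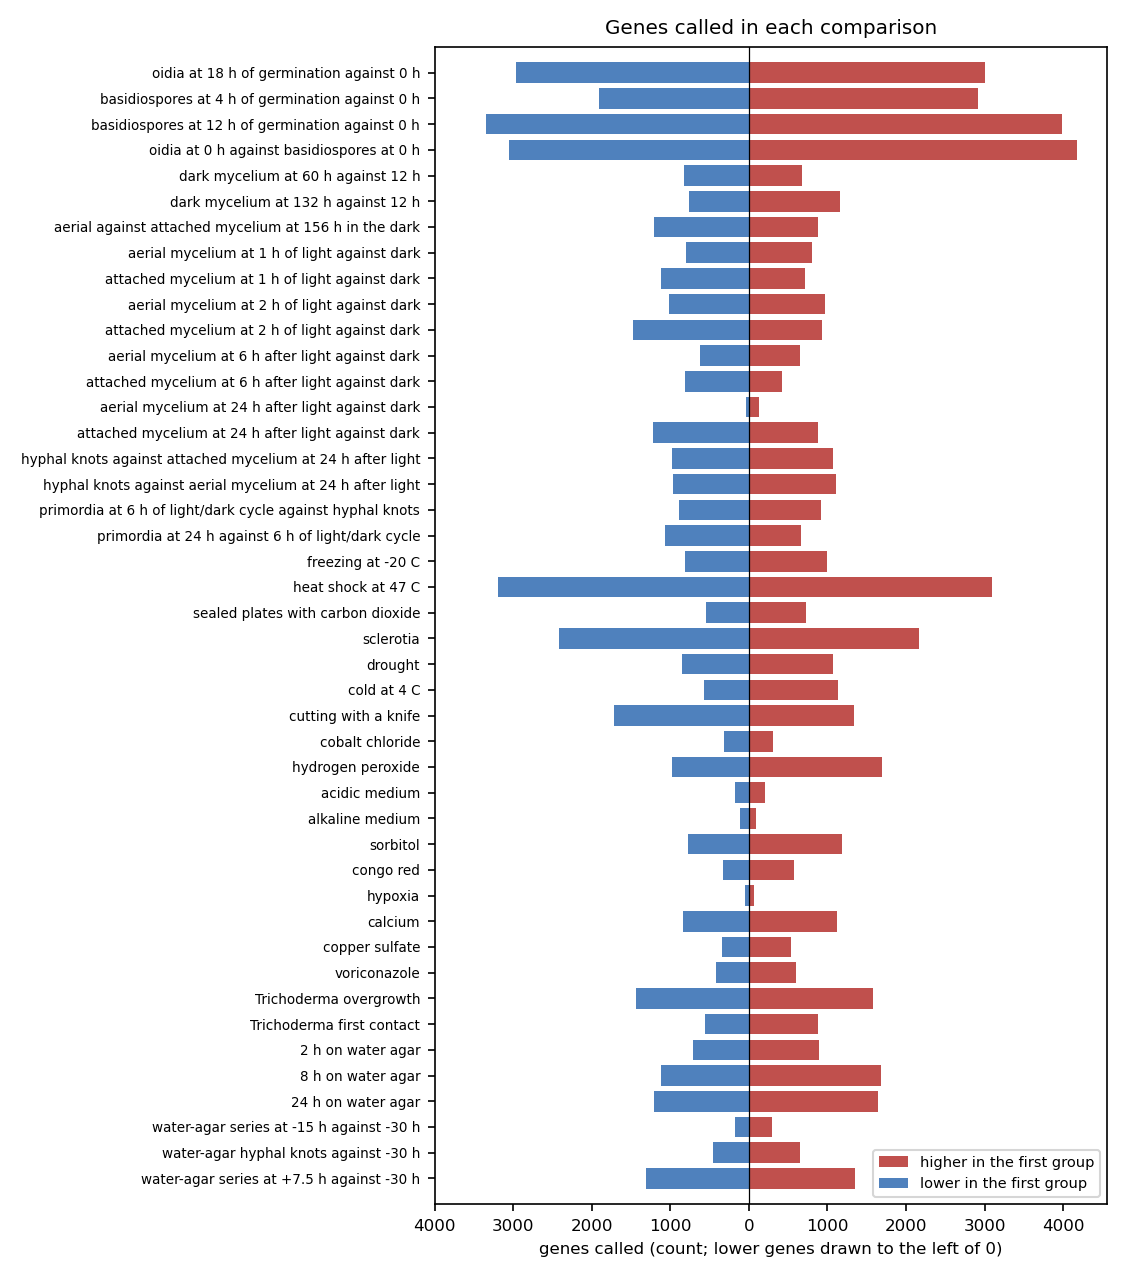
Number of genes called in each comparison (horizontal axis, count of genes, lower genes drawn to the left of 0), with each comparison named on the vertical axis. Red bars are genes higher in the condition named first and blue bars genes lower in it, and the heat shock comparison reaches 3092 higher and 3194 lower genes where hypoxia reaches 60 higher and 55 lower.

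Transcripts of the resting spore fell within hours of germination. The spore set, defined on the ungerminated basidiospores themselves and so not independent evidence of its direction, lay at −2.33 ± 0.38 (log2, mean ± SD, n = 3) after 4 h, −5.05 ± 0.30 after 8 h and −7.91 ± 0.43 after 12 h. The oidium set, which shares no library with the basidiospores, also fell, by 4 h in 25 of 100 genes with 4 higher (22 lower and 3 higher adjusted over the list alone) and by 12 h in 67 of 100 with 2 higher. Its median was −0.84 at 4 h (adjusted p = 2.79e-05, and adjusted p = 0.399 with an estimated correlation). It was −2.87 at 12 h (adjusted p = 9.65e-08, and adjusted p = 0.305 with an estimated correlation). At 12 h the sclerotium set fell too, in 50 of 82 genes with 11 higher (adjusted p = 1.47e-05, and adjusted p = 0.44 with an estimated correlation). CopciAB_379049.T0 (scaffold 11, 352680 to 355429, 5 exons) went from 75689 ± 18112 to 17.7 ± 13.7 CPM, a log2 change of −12.05 ± 0.95 (SE, adjusted p = 1.18e-08). CopciAB_503969.T0 (scaffold 5, 3116448 to 3119019, 10 exons), at 0 counts in ungerminated basidiospores, was at least 244-fold higher at 12 h, with 17.6, 20.2 and 19.2 CPM in the 3 libraries.

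In basidiospores, 2914 genes were higher and 1908 lower at 4 h than at 0 h, and 3989 were higher and 3349 lower at 12 h. The balance at 4 h depended on the scaling, with 2469 higher and 2480 lower genes under RLE factors and 2460 and 2491 with DESeq2. It also depended on each ungerminated library, since without library 1, 2 or 3 the split was 2250 to 2421, 2227 to 2465 and 2510 to 2556. The median change of all tested genes was 0.14 at 4 h and 0.21 at 12 h, so small changes should be read against that shift.

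Oidia that had germinated for 18 h differed from resting oidia in 5976 of 11272 tested genes, 3010 higher and 2966 lower, which is 53.0%. The spore set fell in 60 of 100 genes with 6 higher, at a median of −2.11 (adjusted p = 1.16e-06, and adjusted p = 0.556 with an estimated correlation). The sclerotium set fell in 50 of 82 genes with 10 higher, at a median of −1.79 (adjusted p = 4.48e-05, and adjusted p = 0.474 with an estimated correlation). The aerial set fell in 37 of 84 with 10 higher (adjusted p = 0.00279, and adjusted p = 0.103 with an estimated correlation). The hypoxia set rose in 30 of 56 genes with 8 lower, at a median of 1.38 (adjusted p = 0.00255, and adjusted p = 0.48 with an estimated correlation). CopciAB_372973.T0 (scaffold 3, 2725261 to 2726328, 5 exons) rose from 1.49 ± 1.23 to 601 ± 151 CPM (log2 change 8.52 ± 0.64, adjusted p = 2.65e-09). CopciAB_1000615.T0 (scaffold 3, 529048 to 529780, 2 exons) fell from 109 ± 76.7 to 0.254 ± 0.361 CPM. The resting spores of both kinds differed from each other in 7238 genes, 4183 higher and 3055 lower in oidia. There the median of all tested genes was 0.32, and the copper set was lower in oidia in 31 of 71 genes and higher in 13 (adjusted p = 0.0158, and adjusted p = 0.615 with an estimated correlation).

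Mycelium growing in the dark held more of the transcripts of starved mycelium at 132 h than at 12 h. The young mycelium set, defined at 12 and 132 h of the same course and so not independent evidence of its fall, stood at −0.90 ± 0.10 at 36 h, −1.67 ± 0.11 at 60 h and −2.20 ± 0.15 at 132 h. The starvation set, defined against the 60 h libraries of this course and so tested only between 12 and 132 h, rose in 49 of 77 genes and fell in 1 (52 and 1 adjusted over the list alone), at a median of 2.00 (adjusted p = 9.31e-13, and adjusted p = 0.105 with an estimated correlation). The copper set fell at 132 h in 27 of 74 genes with 5 higher (adjusted p = 5.19e-05, and adjusted p = 0.0609 with an estimated correlation). The Trichoderma set fell in 37 of 99 with 12 higher (adjusted p = 7.88e-05, and adjusted p = 0.258 with an estimated correlation). At 60 h the aerial set was lower than at 12 h in 46 of 100 genes and higher in 3 (48 and 4 adjusted over the list alone), at a median of −0.93 (adjusted p = 1.62e-13, and adjusted p = 0.163 with an estimated correlation). The oidium set was lower in 12 of 28 (adjusted p = 9.3e-05, and adjusted p = 0.261 with an estimated correlation). Against 12 h, 673 genes were higher and 829 lower at 60 h, and 1159 higher and 765 lower at 132 h.

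At 156 h in the dark the hyphae standing in the air carried far less of the starvation transcripts than the mycelium attached to the agar. Of 99 starvation genes, 56 were lower and 8 higher in aerial mycelium (62 and 8 adjusted over the list alone), at a median of −2.41 (adjusted p = 1.31e-11, and adjusted p = 0.191 with an estimated correlation). The hypoxia set was lower in 24 of 58 genes and higher in 3 (adjusted p = 0.00322, and adjusted p = 0.628 with an estimated correlation). The young mycelium set was higher in 26 of 100 and lower in 9 (adjusted p = 0.0134, and adjusted p = 0.48 with an estimated correlation). CopciAB_546727.T0 (scaffold 5, 3420377 to 3421568, 2 exons) was higher in aerial mycelium by 5.90 ± 1.02 on the log2 scale. CopciAB_448984.T0 (scaffold 7, 603634 to 604358, 1 exon), at 0 counts in aerial mycelium, was at least 991-fold lower there, against 153, 115 and 11.9 CPM in the attached libraries, but was not called in a fit of these groups alone. CopciAB_438797.T0 (scaffold 11, 1722204 to 1723246, 4 exons) was at 8.58 ± 3.59 CPM in aerial and 2890 ± 948 CPM in attached mycelium. Together 877 genes were higher and 1209 lower in aerial than in attached mycelium. On scaffold 6, from 69859 to 83994, 7 consecutive tested genes were all higher in aerial mycelium, where the longest such run in 200 shuffles of the calls was 5.

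Both compartments differed from the dark after 1 h of light. In aerial mycelium 809 genes rose and 800 fell, and in attached mycelium 716 rose and 1121 fell. The light set, defined in aerial mycelium, rose in 53 of 100 genes of attached mycelium and fell in 8 (57 and 8 adjusted over the list alone), at a median of 1.38 (adjusted p = 1.04e-14, and adjusted p = 0.0283 with an estimated correlation). The genes called overlapped between compartments, which have separate controls, in 309 genes higher in both, against 49.0 for independent lists (Fisher's exact test, p = 3.1e-185). Another 360 were lower in both, against 75.9 (Fisher's exact test, p = 1.4e-170), and 32 went opposite ways. Across the 11812 genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.43 and a Spearman rho of 0.51. Both controls are dark mycelium of the same age, and a library batch common to them would add to this overlap. In aerial mycelium the primordium set rose after 1 h in 21 of 100 genes with 4 lower (22 and 4 adjusted over the list alone), at a median of 0.37 (adjusted p = 0.000304, and adjusted p = 0.376 with an estimated correlation). The light and primordium sets share 17 genes, and the primordia had been in a cycle of light and dark. CopciAB_500405.T0 (scaffold 7, 634533 to 636078, 3 exons) went from 2.45 ± 2.75 to 1282 ± 437 CPM in aerial mycelium after 1 h of light (adjusted p = 7.21e-10). CopciAB_450946.T0 (scaffold 7, 782931 to 783548, 4 exons) fell from 88.8 ± 30.1 to 0.494 ± 0.653 CPM.

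In attached mycelium the starvation set was lower after 1 h of light than in the dark and higher 24 h after light. Of 99 starvation genes, 71 fell and 0 rose after 1 h of light (73 and 0 adjusted over the list alone), at a median of −2.32 (adjusted p = 1.86e-19, and adjusted p = 0.0609 with an estimated correlation). After 2 h of light 70 fell and 0 rose, at a median of −3.33 (adjusted p = 5.82e-20, and adjusted p = 0.0606 with an estimated correlation). At 6 h after light 58 were lower and 1 higher than in the dark (adjusted p = 1.96e-18, and adjusted p = 0.0708 with an estimated correlation). At 24 h after light 70 were higher and 2 lower than in the dark (74 and 2 adjusted over the list alone), at a median of 2.32 (adjusted p = 3.87e-26, and adjusted p = 0.0344 with an estimated correlation). Relative to dark attached mycelium, whose own libraries spread by 0.98 (SD, n = 3), the set stood at −2.01 ± 0.20 after 1 h of light, −1.70 ± 0.49 at 6 h, −1.05 ± 0.26 at 12 h, 0.36 ± 0.70 at 18 h and 2.40 ± 0.34 at 24 h after light. The fall from the dark to 1 h was not separated from a library batch shared by the dark and 24 h libraries. In aerial mycelium it stayed between −0.06 and 0.82 at the same times. After 2 h of light 968 genes were higher and 1018 lower in aerial mycelium and 932 higher and 1481 lower in attached mycelium. At 6 h after light the counts were 647 and 620 in aerial mycelium, with a total of 837 without library 2 of that group, and 424 and 818 in attached mycelium.

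The light set stood lower 24 h after light than after 1 h of light. In attached mycelium it stood at 1.47 ± 0.26 after 1 h of light, 0.99 at 6 h, 0.68 at 18 h and −0.09 ± 0.06 at 24 h after it. It was called after 2 h of light, with 52 of 100 genes higher and 9 lower (adjusted p = 2.49e-10, and adjusted p = 0.0609 with an estimated correlation). It was also called 6 h after light, with 34 higher and 3 lower (adjusted p = 1.12e-10, and adjusted p = 0.0603 with an estimated correlation). In aerial mycelium, on whose libraries it was defined, it stood at 2.72 ± 0.04 after 1 h of light, 1.70 at 18 h and 0.66 ± 0.20 at 24 h after it, a fall in which time and a library batch were not separated. The oidium set was called lower there after 1 h of light, with 13 of 76 genes lower and 3 higher, at a median of −1.06 (adjusted p = 0.00151, and adjusted p = 0.376 with an estimated correlation). It was also lower after 2 h of light, at −1.13 (adjusted p = 0.0016, and adjusted p = 0.376 with an estimated correlation), and 6 h after it, at −0.70 (adjusted p = 0.0065, and adjusted p = 0.474 with an estimated correlation). It was called higher 24 h after light, with 17 of 76 genes higher and 0 lower (47 and 1 adjusted over the list alone), at a median of 2.23 (adjusted p = 3.33e-32, and adjusted p = 0.000563 with an estimated correlation). The sclerotium set rose in 9 of 97 genes and fell in 0 (24 and 0 adjusted over the list alone), at a median of 1.12 (adjusted p = 3.27e-12, and adjusted p = 0.0393 with an estimated correlation). The hyphal knot set rose in 23 of 100 with 0 lower (42 and 0 adjusted over the list alone), at a median of 1.26 (adjusted p = 1.09e-15, and adjusted p = 0.0909 with an estimated correlation).

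At 24 h after light 129 genes were higher and 32 lower in aerial mycelium than in the dark, while 877 were higher and 1221 lower in attached mycelium. The aerial count of 161 fell to 49, 59 and 85 without dark aerial library 1, dark aerial library 2 and 24 h aerial library 1. It was 266 with DESeq2 and 261 in a fit of all groups. All of these counts come from fits without pairing.

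**Figure D2:**
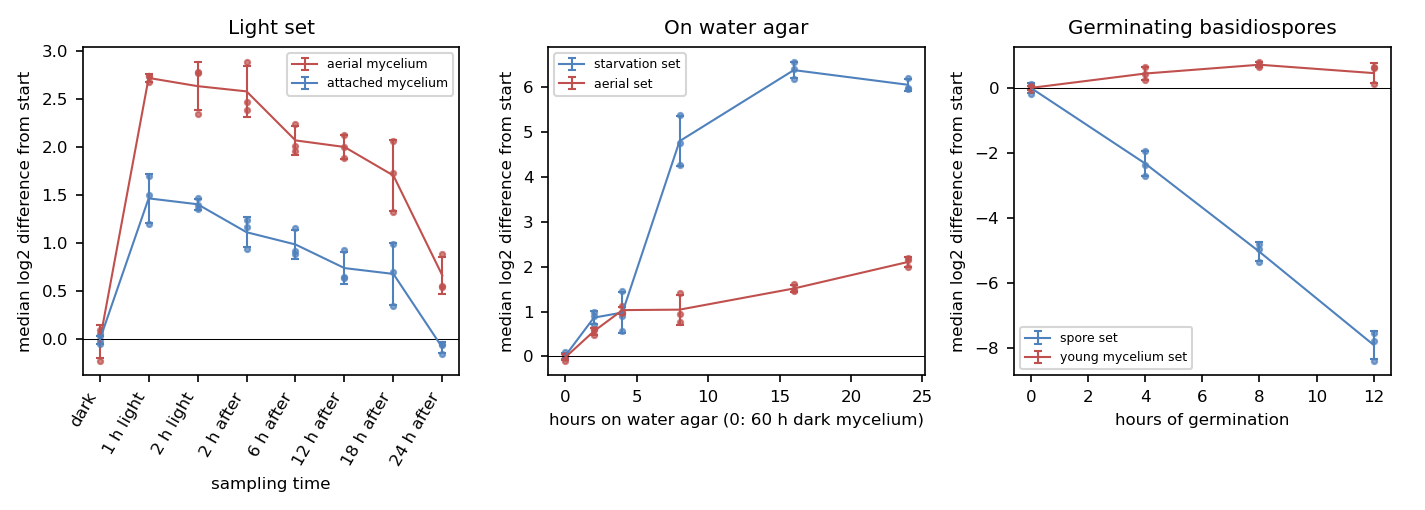
Course of response sets as the median log2 difference from the starting group (vertical axes) against sampling time (left, light set in aerial and attached mycelium), hours on water agar (middle) and hours of germination of basidiospores (right), with points for libraries and lines with bars for the mean and SD of 3 libraries. The light set falls from 1.47 to −0.09 in attached mycelium, the starvation set climbs to 6.05 at 24 h on water agar and the spore set falls to −7.91, where the light set in aerial mycelium, the starvation set and the spore set were defined on libraries of the same course.

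Hyphal knots collected 24 h after light held less of the starvation transcripts than attached mycelium of the same age. Of 99 starvation genes, 75 were lower and 4 higher in knots than in attached mycelium of the same age (81 and 5 adjusted over the list alone), at a median of −3.62 (adjusted p = 4.42e-45, and adjusted p = 0.00252 with an estimated correlation). The sclerotium set was lower in 50 of 97 genes and higher in 8 (54 and 11 adjusted over the list alone), at a median of −1.94 (adjusted p = 9.55e-12, and adjusted p = 0.0434 with an estimated correlation). The spore set was lower in 33 of 79 and higher in 3 (adjusted p = 2.91e-06, and adjusted p = 0.163 with an estimated correlation). Against aerial mycelium of the same age the aerial set was lower in knots in 89 of 100 genes and higher in 1 (92 and 1 adjusted over the list alone), at a median of −2.70 (adjusted p = 9.3e-46, and adjusted p = 0.00252 with an estimated correlation). The starvation set was not called there, with 23 of 99 genes higher and 12 lower, at a median of 0.29 (adjusted p = 0.193). The oidium set was lower in 34 of 76 and higher in 5 (adjusted p = 2.12e-09, and adjusted p = 0.0805 with an estimated correlation). CopciAB_527180.T0 (scaffold 11, 68588 to 70180, 6 exons), at 0 counts in attached mycelium, was at least 221-fold higher in knots, with 41.7, 3.53 and 9.53 CPM in the 3 libraries. CopciAB_1001041.T0 (scaffold 4, 3274726 to 3276030, 1 exon), at 0 counts in knots, was at least 134-fold lower there, with 10.3, 26.2 and 4.38 CPM in the attached libraries. CopciAB_448984.T0 was at 0.872 ± 0.240 CPM in knots and 824 ± 435 CPM in attached mycelium. In all, 1067 genes were higher and 984 lower in knots than in attached mycelium, and 1106 higher and 966 lower than in aerial mycelium. A run of 6 consecutive tested genes on scaffold 1, from 314472 to 342367, was higher in knots than in aerial mycelium, where shuffled calls gave at most 5.

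The knot set stayed high in primordia, samples named here from a light and dark cycle, where stage and renewed light were not separated. Relative to dark attached mycelium, the hyphal knot set stood at 3.55 ± 0.94 in the knots it was defined on and between 3.78 and 4.54 in primordia. The primordium set, defined as higher in 24 h primordia than in these knots and so not independent evidence of its rise, stood at 0.73 in knots, at 3.26 in 6 h primordia and at 4.71 ± 0.16 in 24 h primordia. From knots to 6 h primordia the aerial set rose in 31 of 100 genes and fell in 5 (34 and 5 adjusted over the list alone), at a median of 0.76 (adjusted p = 0.000246, and adjusted p = 0.5 with an estimated correlation). The oidium set rose in 16 of 76 and fell in 2 (adjusted p = 7.58e-05, and adjusted p = 0.273 with an estimated correlation). From 6 h to 24 h the aerial set fell in 26 of 100 genes and rose in 3 (adjusted p = 0.00262, and adjusted p = 0.599 with an estimated correlation). CopciAB_427537.T0 (scaffold 10, 121935 to 122669, 4 exons) fell from 12.8 ± 9.57 to 0.260 ± 0.181 CPM. The counts were 917 higher and 886 lower at 6 h than in knots, with 543 and 801 without knot library 3. They were 669 higher and 1068 lower at 24 h than at 6 h. That is a total of 1737 that was 1073 without 6 h library 1.

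In mycelium moved from rich medium to water agar most of the rise of the starvation set came between 4 and 8 h. The starvation set, defined at the end of this course, stood at 0.86 ± 0.14 after 2 h, 0.98 ± 0.46 after 4 h, 4.80 ± 0.56 after 8 h, 6.38 ± 0.18 after 16 h and 6.05 ± 0.13 after 24 h. The aerial set, defined on other libraries, rose in 27 of 99 genes with 5 lower after 2 h (adjusted p = 1.57e-05, and adjusted p = 0.217 with an estimated correlation). It rose in 50 with 6 lower after 8 h (adjusted p = 7.77e-09, and adjusted p = 0.0909 with an estimated correlation). After 24 h it rose in 71 of 99 genes and fell in 0 (73 and 1 adjusted over the list alone), at a median of 2.19 (adjusted p = 1.28e-19, and adjusted p = 0.02 with an estimated correlation). The 60 h control itself held less of the aerial set than 12 h mycelium, with 46 of 100 genes lower and 3 higher, at a median of −0.93. Low values of the set in that control would add to these rises. The hypoxia set fell after 2 h in 24 of 58 genes with 2 higher (adjusted p = 1.37e-08, and adjusted p = 0.163 with an estimated correlation). After 24 h it fell in 31 with 4 higher (adjusted p = 3.23e-07, and adjusted p = 0.204 with an estimated correlation). CopciAB_407854.T0 (scaffold 8, 469670 to 470627, 3 exons, overlapping a gene on the other strand) and CopciAB_494544.T0 (scaffold 4, 1194024 to 1194985, 4 exons), both at 0 counts in 60 h mycelium, were at least 3797-fold (364 ± 64.5 CPM) and at least 542-fold (52.9 ± 17.2 CPM) higher after 24 h. Against 60 h mycelium, 887 genes were higher and 706 lower after 2 h, 1679 higher and 1121 lower after 8 h, and 1645 higher and 1210 lower after 24 h. A run of 7 consecutive tested genes on scaffold 6, from 2786010 to 2809037, was higher after 2 h, where shuffled calls gave at most 5.

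Hyphal knots also formed on 1% water agar, sampled from 30 h before knots to 7.5 h after them. The aerial set rose before knots appeared, 15 h ahead of them, in 45 of 100 genes with 1 lower (51 and 1 adjusted over the list alone), at a median of 1.01 (adjusted p = 5.62e-22, and adjusted p = 0.0388 with an estimated correlation). The starvation set rose in 23 of 100 with 0 lower (37 and 1 adjusted over the list alone, adjusted p = 1.58e-14, and adjusted p = 0.35 with an estimated correlation). At the knots the oidium set was higher than 30 h before in 16 of 42 genes and lower in 0, at a median of 2.26 (adjusted p = 1.98e-06, and adjusted p = 0.248 with an estimated correlation). The young mycelium set was lower in 37 of 98 and higher in 6, at a median of −0.80 (adjusted p = 1.99e-10, and adjusted p = 0.179 with an estimated correlation). At 7.5 h after knots the sclerotium set was higher in 36 of 75 genes and lower in 0, at a median of 1.74 (adjusted p = 7.02e-08, and adjusted p = 0.17 with an estimated correlation). The young mycelium set was lower in 50 of 98 and higher in 14 (adjusted p = 7.41e-07, and adjusted p = 0.273 with an estimated correlation). CopciAB_362513.T0 (scaffold 3, 923635 to 924666, 6 exons, overlapping a gene on the other strand) was higher at the knots by 7.34 ± 0.52 on the log2 scale. CopciAB_441597.T0 (scaffold 11, 1503158 to 1504503, 5 exons) changed by −5.44 ± 0.57. Counts against 30 h before were 299 higher and 174 lower at 15 h before, 655 and 461 at the knots, and 1345 and 1313 at 7.5 h after.

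Knots formed after light and knots formed on water agar, measured against different references, changed more genes in opposite directions than in the same one, and the direction depended on the reference. Of 10993 genes tested in both, 71 were higher in both, against 57.1 for independent lists (Fisher's exact test, p = 0.0536), and 34 lower in both, against 39.0 (Fisher's exact test, p = 0.441). Opposite calls numbered 310, against 95.6 for independent lists, and the log2 changes correlated across genes with a Pearson r of −0.20 and a Spearman rho of −0.23. Measured against dark attached mycelium, a reference chosen after the data were seen, the direction turned, with 272 genes called the same way, 58 opposite and a Pearson r of 0.22. The higher overlap had a p of 0.0239 under RLE factors, 0.0155 with DESeq2 and 0.0261 without the filter (Fisher's exact test). The hyphal knot set stood at −0.16 in water-agar knots and at 0.40 after them.

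**Figure D3:**
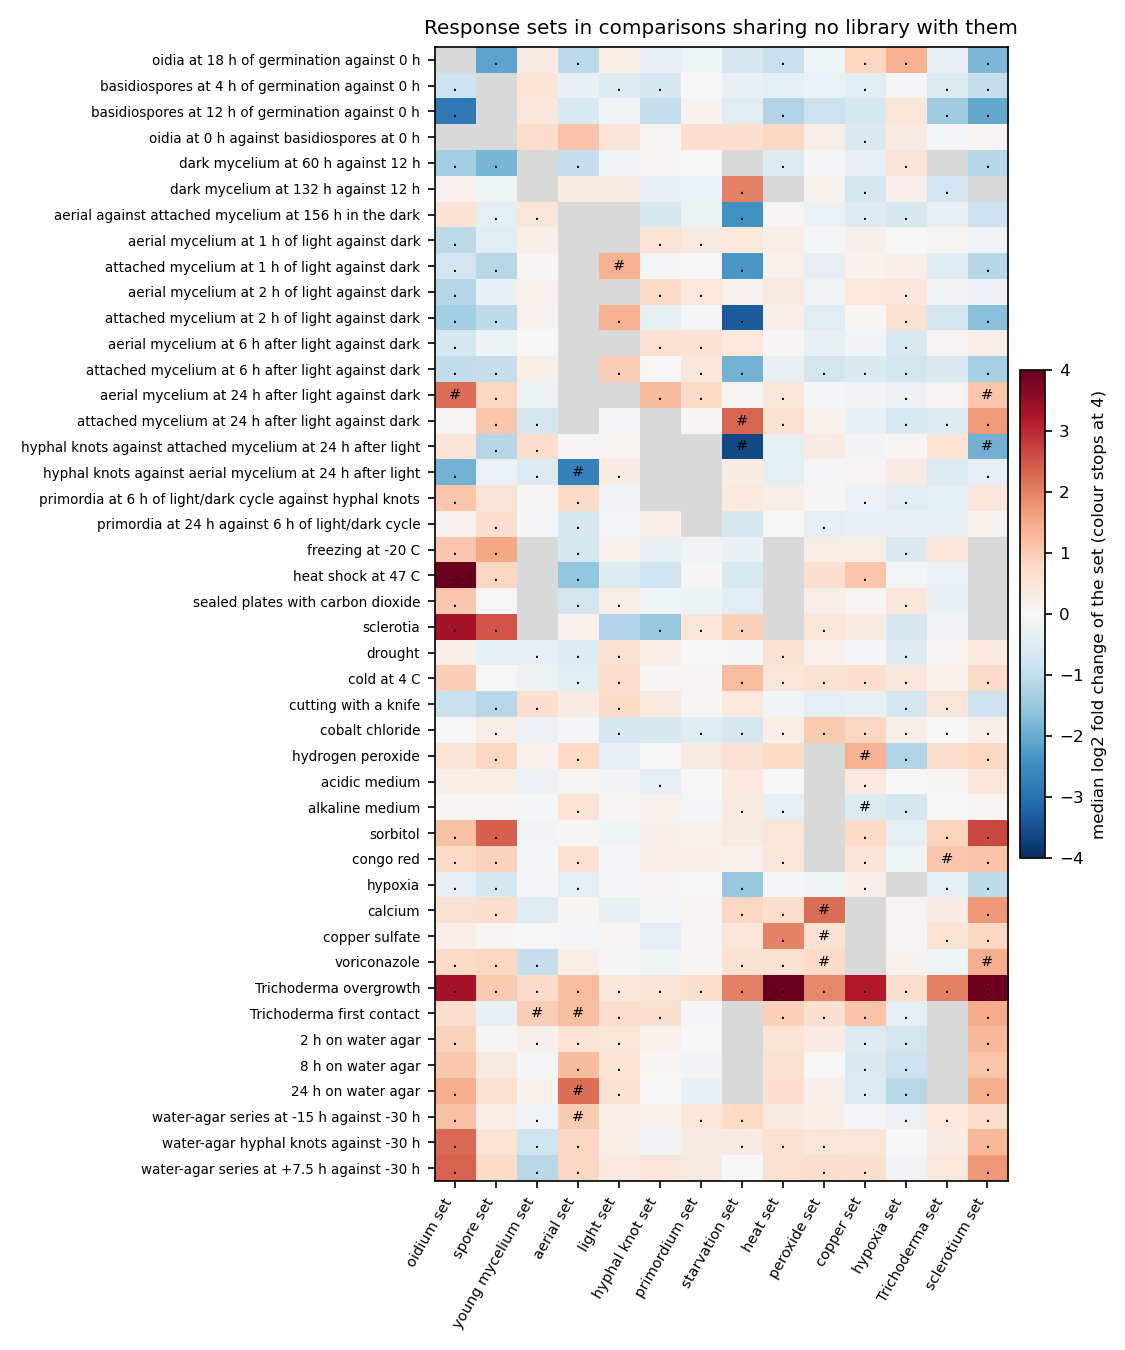
Median log2 fold change (colour, stopping at 4 in either direction) of the 14 response sets (horizontal axis) in each of the 44 comparisons (vertical axis). A dot marks a camera call with the preset correlation and # a call that also holds with an estimated one (18 in all), and grey cells share a library with the set's definition or were not tested.

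Heat shock at 47 °C for 2 h changed more of the transcriptome than any other stress tested. It raised 3092 genes and lowered 3194, 55.9% of 11251, and 463 of the higher genes rose at least 16-fold. The oidium set rose in 37 of 49 genes and fell in 3, at a median of 4.24 (adjusted p = 1.19e-07, and adjusted p = 0.098 with an estimated correlation). The copper set rose in 37 of 75 with 10 lower, at a median of 1.10 (adjusted p = 0.00292, and adjusted p = 0.248 with an estimated correlation). The aerial set fell in 56 of 99 genes with 6 higher (adjusted p = 3.59e-05, and adjusted p = 0.303 with an estimated correlation). CopciAB_483695.T0 (scaffold 11, 2069628 to 2070997, 4 exons), at 0 counts in control mycelium, reached 971 ± 65.7 CPM, at least 9432-fold higher. CopciAB_423239.T0 (scaffold 4, 3269316 to 3270320, 3 exons) went from 1.09 ± 0.707 to 48961 ± 11129 CPM (log2 change 15.42 ± 1.23, adjusted p = 5.38e-07).

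Freezing at −20 °C for 30 min raised 991 genes and lowered 814, and resting-spore transcripts were among those that rose. The spore set rose in 36 of 70 genes and fell in 3 (38 and 4 adjusted over the list alone), at a median of 1.56 (adjusted p = 8.78e-11, and adjusted p = 0.354 with an estimated correlation). The oidium set rose in 16 of 49 with 1 lower (adjusted p = 0.000189, and adjusted p = 0.248 with an estimated correlation). Sclerotia, the dense resting bodies collected after 4 weeks and possibly carrying some mycelium according to the labels, held 2172 higher and 2417 lower genes than 132 h mycelium. In sclerotia the oidium set rose in 28 of 49 genes with 0 lower, at a median of 3.33 (adjusted p = 1.61e-06, and adjusted p = 0.14 with an estimated correlation). The spore set rose there in 41 of 70 with 8 lower, at 2.51 (adjusted p = 8.65e-07, and adjusted p = 0.474 with an estimated correlation). The hyphal knot set fell in 41 of 81 with 16 higher (adjusted p = 0.00258, and adjusted p = 0.217 with an estimated correlation). A run of 13 consecutive tested genes on scaffold 8, from 46287 to 94016, was lower in sclerotia, where shuffled calls gave at most 8. Of the 13, 2 share reads with other models. In sealed plates that gather carbon dioxide, 727 genes rose and 547 fell. The hypoxia set rose in 21 of 58 genes with 0 lower, at a median of 0.49 (adjusted p = 3.46e-09, and adjusted p = 0.202 with an estimated correlation). The aerial set fell in 23 of 99 with 1 higher (adjusted p = 3.23e-07, and adjusted p = 0.213 with an estimated correlation).

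Cold, drought and cutting, which share 84 h control mycelium, each raised part of the light set. It rose in 38 of 100 genes with 5 lower in the cold (42 and 5 adjusted over the list alone, adjusted p = 5.16e-06, and adjusted p = 0.185 with an estimated correlation). It rose in 34 with 16 lower under drought (adjusted p = 0.00563, and adjusted p = 0.376 with an estimated correlation) and in 37 with 16 lower after cutting (adjusted p = 0.00151, and adjusted p = 0.35 with an estimated correlation). In the cold, at 4 °C for 4 h, the starvation set also rose in 31 of 82 genes with 4 lower, at a median of 1.23 (adjusted p = 1.41e-06, and adjusted p = 0.376 with an estimated correlation). After cutting, the young mycelium set rose in 37 of 100 genes with 13 lower (adjusted p = 0.000252, and adjusted p = 0.397 with an estimated correlation). The hypoxia set fell in 23 of 58 with 2 higher (adjusted p = 0.000805, and adjusted p = 0.696 with an estimated correlation). Cold raised 1137 genes and lowered 578, drought raised 1077 and lowered 846, and cutting raised 1342 and lowered 1720. Low values of the light set in the shared control would give all of these rises. Looked at afterwards, the mean share of counts in 3 repeat-like gene models on scaffolds 16 and 20 was 0.136% in the control. It was 1.68% in the cold, 1.79% under drought and 0.616% after cutting. In aerial mycelium it was 0.337% in the dark and 2.12% after 1 h of light. A library batch was not separated from the treatments.

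Hydrogen peroxide at 1 mM for 3 h raised 1698 genes and lowered 983. The copper set rose in 44 of 75 genes with 6 lower, at a median of 1.38 (adjusted p = 1.5e-10, and adjusted p = 0.0307 with an estimated correlation). The hypoxia set fell in 33 of 58 with 10 higher, at a median of −1.20 (adjusted p = 2.89e-05, and adjusted p = 0.528 with an estimated correlation). CopciAB_482047.T0 (scaffold 2, 672011 to 672742, 4 exons), at 0 counts in the control culture, was at least 446-fold higher, with 6.38, 25.3 and 59.1 CPM in the peroxide libraries. CopciAB_31906.T0 (scaffold 2, 3475660 to 3476895, 3 exons) fell from 640 ± 174 to 43.8 ± 2.56 CPM. Sorbitol at 10% raised 1179 genes and lowered 776. The spore set rose in 40 of 64 genes and fell in 2, at a median of 2.40 (adjusted p = 9.97e-12, and adjusted p = 0.25 with an estimated correlation). The sclerotium set rose in 46 of 83 and fell in 11, at 2.67 (adjusted p = 7.57e-09, and adjusted p = 0.367 with an estimated correlation). Congo red at 1%, a dye that binds cell wall polymers, raised 578 genes and lowered 336. The Trichoderma set rose with it in 42 of 97 genes and fell in 4 (50 and 5 adjusted over the list alone), at a median of 1.11 (adjusted p = 3.36e-12, and adjusted p = 0.0354 with an estimated correlation). On scaffold 10, from 1806687 to 1817545, a run of 6 consecutive tested genes was lower with congo red, where shuffled calls gave at most 4.

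The copper set moved opposite ways with the acidity of the medium. At pH 4 it rose in 15 of 75 genes and fell in 0 (16 and 1 adjusted over the list alone), at a median of 0.38 (adjusted p = 3.52e-06, and adjusted p = 0.0805 with an estimated correlation). At pH 9 it fell in 16 and rose in 0 (19 and 1 adjusted over the list alone), at −0.56 (adjusted p = 1.94e-11, and adjusted p = 0.0283 with an estimated correlation). Both comparisons use the same control libraries, and the difference between them was not tested. At pH 9 the hypoxia set fell in 7 of 58 genes and rose in 0 (14 and 0 adjusted over the list alone), at −0.70 (adjusted p = 3.09e-14, and adjusted p = 0.258 with an estimated correlation). At pH 4, 207 genes rose and 181 fell, a total of 388 that was 185 without pH 4 library 1 and 243 without control library 1. At pH 9, 92 rose and 117 fell, a total of 209 that was 357 with DESeq2 and 93, 98, 129, 55 and 93 without control library 1, control library 2 and pH 9 libraries 1, 2 and 3.

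With cobalt chloride at 2 mM the peroxide and copper sets were called higher, with the preset correlation only. By its title the cobalt culture was 7 days old and had 2 h of light, then 22 h of darkness. The titles of its control state neither age nor light, so the labels do not separate cobalt from these. The peroxide set rose in 39 of 91 genes with 2 lower (46 and 2 adjusted over the list alone), at a median of 1.05 (adjusted p = 2.09e-19, and adjusted p = 0.177 with an estimated correlation). The copper set rose in 28 of 73 with 2 lower (31 and 3 adjusted over the list alone), at 0.81 (adjusted p = 8.17e-14, and adjusted p = 0.185 with an estimated correlation). The starvation set fell in 19 of 70 with 2 higher (adjusted p = 3.2e-08, and adjusted p = 0.273 with an estimated correlation). The Trichoderma set was called higher with a mean of 0.52 but a median of −0.02 (adjusted p = 0.042, and adjusted p = 0.64 with an estimated correlation). Cobalt raised 310 genes and lowered 317, a total of 627 that was 354 without cobalt library 3.

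Hypoxia for 24 h raised 60 genes and lowered 55 of 10256 tested. The starvation set fell in 17 of 95 genes with 0 higher (40 and 0 adjusted over the list alone), at a median of −1.53 (adjusted p = 3.07e-29, and adjusted p = 0.35 with an estimated correlation). CopciAB_544842.T0 (scaffold 8, 1551030 to 1551687, 2 exons) fell from 11.8 ± 2.43 to 0.446 ± 0.410 CPM. The total of 115 was 274 with DESeq2 (122 higher, 152 lower) and 233 in a fit of all groups (95 higher, 138 lower), so the balance turned. It was 19, 24, 52 and 76 without control library 2, control library 3, hypoxia library 3 and hypoxia library 2. Without hypoxia library 1 the split was 84 higher to 38 lower.

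Calcium for 24 h, copper for 6 h and voriconazole at 0.5 µg/ml for 48 h share a control without a stated time. Treatment and time were therefore not separated. In that control library 3 stood apart. It held 2893429 counts, and 58.0% of its nonzero values were not whole, against 33.2% and 32.0% in libraries 1 and 2. In it 787 of 6470 genes lay beyond 4-fold of the other two, against 133 and 100. No set test was repeated without this library. With calcium at 200 mM, 1123 genes rose and 840 fell, and the peroxide set rose in 56 of 98 genes with 2 lower (59 and 4 adjusted over the list alone), at a median of 2.24 (adjusted p = 3.98e-20, and adjusted p = 0.00252 with an estimated correlation). A run of 8 consecutive tested genes on scaffold 11, from 116333 to 156524, was higher with calcium, where shuffled calls gave at most 5. With copper sulfate at 2 mM, 539 genes rose and 344 fell. The heat set rose in 28 of 68 genes with 0 lower (35 and 0 adjusted over the list alone), at a median of 1.99 (adjusted p = 3.85e-12, and adjusted p = 0.238 with an estimated correlation). The peroxide set rose in 29 of 98 with 4 lower (31 and 4 adjusted over the list alone), at 0.62 (adjusted p = 5.32e-06, and adjusted p = 0.0388 with an estimated correlation). CopciAB_367347.T0 (scaffold 1, 861145 to 862638, 7 exons) reached 3098, 237 and 281 CPM in the copper libraries against a mean of 0.287 CPM. With voriconazole, an inhibitor of ergosterol synthesis, 595 genes rose and 423 fell. The sclerotium set rose in 38 of 81 genes with 0 lower (41 and 1 adjusted over the list alone), at a median of 1.46 (adjusted p = 2.01e-14, and adjusted p = 0.0434 with an estimated correlation). The peroxide set rose in 30 of 98 with 2 lower (32 and 5 adjusted over the list alone), at 0.76 (adjusted p = 4.04e-07, and adjusted p = 0.0307 with an estimated correlation). It thus rose with calcium, copper and voriconazole alike, and low values of the set in their shared control would give all of these rises.

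These counts depended on the libraries fitted. In a fit of the compared groups alone copper called 96 genes (79 higher, 17 lower) and voriconazole 345 (233 higher, 112 lower). In a fit of all groups calcium called 2984 (1404 higher, 1580 lower), copper 1889 (976 and 913) and voriconazole 1912 (904 and 1008). The balance thus turned to lower genes for calcium and voriconazole. Without copper library 1 the copper count was 480, and without voriconazole library 1, 2 or 3 the voriconazole count was 469, 537 or 560.

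First contact with Trichoderma, a fungus that attacks other fungi, raised 875 genes and lowered 553. The aerial set rose in 47 of 99 genes with 4 lower (50 and 4 adjusted over the list alone), at a median of 1.20 (adjusted p = 4.86e-14, and adjusted p = 0.0388 with an estimated correlation). Its control is the 60 h mycelium also used for water agar, so low values of the aerial set there would give both rises. The young mycelium set rose in 47 of 100 with 12 lower (48 and 13 adjusted over the list alone), at 0.97 (adjusted p = 8.86e-11, and adjusted p = 0.0032 with an estimated correlation). The copper set rose in 34 of 75 with 1 lower (adjusted p = 3.87e-10, and adjusted p = 0.09 with an estimated correlation). CopciAB_428944.T0 (scaffold 3, 3269979 to 3271373, 6 exons) rose from 3.13 ± 1.77 to 329 ± 50.4 CPM. CopciAB_50839.T0 (scaffold 3, 3283152 to 3283827, 3 exons) rose from 2.22 ± 1.73 to 199 ± 125 CPM.

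Mycelium overgrown by Trichoderma for 60 h held 1583 higher and 1433 lower genes, a total of 3016 that was 1976 without control library 2. The overgrown libraries correlated with one another at only 0.695 to 0.742, and each was closer on average to another group (0.731 to 0.744). The heat set rose in 37 of 47 genes with 0 lower (39 and 0 adjusted over the list alone), at a median of 4.78 (adjusted p = 1.6e-22, and adjusted p = 0.0606 with an estimated correlation). The sclerotium set rose in 40 of 56 with 0 lower, at 3.92 (adjusted p = 5.82e-20, and adjusted p = 0.0561 with an estimated correlation). The copper set rose in 57 of 70 with 2 lower, at 3.21 (adjusted p = 5.23e-23, and adjusted p = 0.317 with an estimated correlation). The Trichoderma set rose in 59 of 95 genes with 3 lower, at 2.02 (adjusted p = 8e-14, and adjusted p = 0.0658 with an estimated correlation). The median of all tested genes was −0.12. Genes near 0 in the control passed the count filter only if the overgrown libraries held them, which favours rises of such sets here. First contact and overgrowth, with separate controls, shared 347 higher genes, against 119 for independent lists (Fisher's exact test, p = 1.62e-94), and 213 lower genes, against 77.6 (Fisher's exact test, p = 6.04e-50), while 78 went opposite ways. Reads of Trichoderma, present in both, would add to the shared higher genes. In the overgrown libraries 3 gene models on scaffolds 16 and 20, whose values were nearly all split between copies, took 41.7 ± 20.7% of the counts, against 0.119 ± 0.0772% in the control.

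Stresses with separate controls changed some genes alike. Over 19 stress comparisons in 8 control sets, 281 of 9480 genes were higher in at least 5 sets, where 1000 shuffles gave 14.5 on average and at most 26. Another 200 were lower in at least 5, where shuffles gave 9.90 and at most 21 (the smallest permutation p the shuffles can give, 0.001, for both). With the overgrowth and the control of calcium, copper and voriconazole left out, a choice made after the data were seen, 31 genes were higher and 8 lower in at least 5 of 6 sets, against 0.589 and 0.303. Several of the controls are times of 1 dark course, and a library batch common to them would add to these shared genes. Genes that are easily called in any comparison would also exceed such shuffles, so the excess does not show a common response to stress. Called genes also lay side by side on the scaffolds. In 72 of 88 lists of calls, neighbouring genes called in the same direction outnumbered those of every shuffle.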

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

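In this part the tests of a shared library batch and of a varying share of the counts, the shares of repeat models and the counts of other splits were chosen only after the result was seen.

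The response to light differed between aerial and attached mycelium, which is what singled out both results given here. At 1 h of light a test of the difference itself, aerial change minus attached change, called 353 genes, 284 with a higher and 69 with a lower value in aerial mycelium. Of these, 192 were called in attached mycelium alone, 75 in aerial mycelium alone, 32 in opposite directions, 12 in the same direction and 42 in neither. In a fit of these groups alone the count was 392. Among 100 splits of the samples within each compartment, drawn with a fixed seed, 4 gave a count as large, the real one included, and the highest other split gave 1241. That is a share under 0.05. Splits that mix light and dark libraries also turn the light response into spread, so the share cannot tell a difference between compartments from chance. The split with 1241 genes reversed the light and dark labels in attached mycelium, and the others as large had labels mostly reversed in 1 compartment, which turns the difference of the responses into their sum and points to a structure of the samples, the response that both compartments share. The count of 353 leaned on single libraries. It was 192 without dark aerial library 1, 200 without dark aerial library 2, 194 without dark attached library 1, 230 without dark attached library 2, 202 without aerial 1 h library 3, 209 without attached 1 h library 1 and 219 without attached 1 h library 2.

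At 24 h after light the same test called 973 genes, 695 with a higher and 278 with a lower value in aerial mycelium. Of these, 780 were called in attached mycelium alone, 34 in aerial mycelium alone, 9 in opposite directions, 2 in the same direction and 148 in neither. In a fit of these groups alone the count was 998. Here 5 of 100 splits gave a count as large, the real one included, a share that is not under 0.05, so chance cannot be excluded by it. The splits ignored the pairing of same-numbered aerial libraries. The highest other split, with 1239 genes, had most labels swapped in aerial mycelium, and 3 of the other 4 as large had labels mostly reversed in 1 compartment, the same structure as at 1 h. The count was 621 without dark aerial library 1 and 638 without 24 h aerial library 2, and without 24 h attached library 1 the split was 521 higher to 388 lower.

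The light course also holds a break between 18 h and 24 h, and whether it accounts for either result was not tested. In aerial mycelium the genes called at 1 h kept a median log2 fold, in the direction of the call, of 1.38 at 2 h after light. It was 1.09 at 18 h and 0.27 at 24 h, and in attached mycelium it was 1.46, 0.56 and −0.37. The changes of fold below are log2 as well. If a library batch shared by the dark and the 24 h libraries were the whole cause, the fold would stay level from 2 h to 18 h after light. In attached mycelium it fell by 0.903 in that time, more than the sum of the SDs of 0.139 and with every 18 h library below every 2 h library, which argues against it there. In aerial mycelium the fall was 0.295 against a sum of SDs of 0.279, and the highest 18 h library (1.33) lay above the lowest 2 h library (1.32), so a batch and a decay of the response cannot be told apart, since no time lies between 18 h and 24 h. The share of counts in the repeat models of scaffolds 16 and 20 followed the same break. In aerial mycelium it was 0.216% to 0.494% in the dark and 0.451% to 0.815% at 24 h, against 1.05% to 4.68% from 1 h of light to 18 h after it. In attached mycelium it was 0.485% to 0.887% and 0.270% to 0.718%, against 0.613% to 2.37%. This goes with a batch, and a response of these models to light would give it too. A few gene models that take a varying share of the counts would shift all other genes by 1 factor. From 18 h to 24 h the genes called higher at 1 h changed by a median of −0.852 in aerial and −0.894 in attached mycelium (sums of SDs 0.315 and 0.189). Those called lower changed by 0.789 and 0.944 (0.397 and 0.314). The values were scaled, which takes out most of a common factor beforehand, and both lists were chosen by direction against the dark. Opposite moves were thus favoured in advance, and this test cannot decide whether such a factor contributes. The time since light, which the design names, stays open as an untested explanation.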

How the results depend on the processing

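The fits without the 9 libraries with the lowest totals, without the repeat gene models of scaffolds 16 and 20, without models that share reads and the stress count over fewer control sets were chosen after seeing the data; the other alternatives were fixed before. Of 46 counts of called genes, all 46 stayed within 1.5 times under RLE factors, without the filter and with the replicate block. The same held without the repeat models. All 25 counts refitted without the 9 libraries stayed within that range too. The overgrowth count could not be refitted, since all its overgrown libraries are among the 9. DESeq2 kept 43, a fit of the compared groups alone 41 of 43 and a fit of all groups 41. Depth limits the number of calls, since with the controls of the overgrowth thinned to the overgrown totals 1557 genes were called against 3016. The paired comparison, aerial mycelium at 24 h after light, called 177 genes with the replicate block against 161 without, and the block moved no other count by over 1.5 times (0.739 to 1.10 times). Among the named genes it ended the call of CopciAB_363127.T0 (copper, lower, adjusted p = 0.0258 without and 0.0974 with it). Same-numbered libraries correlated between −0.317 and 0.261 over all comparisons, and in 3 of 44 every library correlated best with its own number. Of 617 settings of named genes, 601 kept the call, 16 lost it and 0 reversed, and the tests of the 34 lists by product name, with their alternatives, were not run for want of gene names.

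Counts that moved, with the cause not tested, were these. With DESeq2 the aerial count at 24 h was 266, pH 9 357 and hypoxia 274 (122 higher, 152 lower). In a fit of all groups the aerial count at 24 h was 261, hypoxia 233 (95 higher, 138 lower), calcium 2984 (1404 and 1580), copper 1889 (976 and 913) and voriconazole 1912 (904 and 1008), so the balance turned to lower genes in hypoxia, calcium and voriconazole. In a fit of the compared groups alone copper was 96 (79 and 17) and voriconazole 345 (233 and 112). Genes changed in most stresses, 481 as reported, were 1361 in at least 4 control sets and 133 in at least 6, by the construction of the minimum, 39 in at least 5 of 6 sets without the overgrowth and the shared control of calcium, copper and voriconazole, and 428 with the replicate block. With an estimated correlation 18 of 247 set calls remained, while sets of 50 genes gave 219, sets of 200 gave 281 and fry 296. The higher overlap of both kinds of knots, 71 genes with Fisher's exact p = 0.0536, passed the threshold with 71 genes under RLE factors (p = 0.0239), 84 with DESeq2 (p = 0.0155) and 68 without the filter (p = 0.0261). Neighbour lists beyond every shuffle numbered 56 with 2 genes on each side and 69 without models that share reads, against 72.

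Leaving out 1 library moved 12 of the 46 counts by over 1.5 times. The range was 837 (without library 2 of that group) to 1275 for aerial mycelium 6 h after light and 49 (without dark library 1) to 172 at 24 h, where 59 and 85 were left without dark library 2 and 24 h library 1. It was 1073 (without 6 h library 1) to 2152 for 24 h primordia and 354 (without cobalt library 3) to 644 for cobalt. At pH 4 it was 185 (without pH 4 library 1) to 511, with 243 without control library 1, and at pH 9 55 (without pH 9 library 2) to 313, with 93 and 98 without control libraries 1 and 2 and 129 and 93 without pH 9 libraries 1 and 3. Hypoxia ranged from 19 (without control library 2) to 135, with 24 without control library 3 and 52 and 76 without hypoxia libraries 3 and 2. Copper ranged from 480 (without copper library 1) to 1093 (555 higher and 538 lower, without control library 1), voriconazole from 469 (without its library 1) to 1216, with 537 and 560 without its libraries 2 and 3, and Trichoderma overgrowth from 1976 (without control library 2) to 3434. The difference between compartments ranged from 192 to 441 at 1 h, where dark aerial libraries 1 and 2, dark attached libraries 1 and 2, aerial 1 h library 3 and attached 1 h libraries 1 and 2 each moved it (192, 200, 194, 230, 202, 209 and 219), and from 621 (without dark aerial library 1) to 1012 at 24 h, with 638 without 24 h aerial library 2.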

Other observations

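In this part the tests of depth and of shared reads, the tests of the knots with another reference and without each library and the counts of other splits were chosen only after the result was seen, as was the region described next.

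A stretch of scaffold 4, from 339640 to 353725, holds 7 gene models on 1 strand that moved together with nutrition and light and was chosen after its values were seen. On water agar 1 of them was higher after 2 h, 7 after 8 h (log2 changes of 4.77 to 7.90) and 7 after 24 h (5.08 to 10.16). In attached mycelium all 7 fell after 1 h of light (−6.43 to −2.06) and after 2 h (−9.69 to −3.55), and all 7 were higher than in the dark 24 h after light (2.48 to 3.76). The fall in attached mycelium was not separated from a library batch shared by the dark and 24 h libraries. In aerial mycelium 0 were called after 1 h of light and 0 at 24 h after it, while 1 was higher after 2 h of light and 1 at 6 h after it. In the dark 6 of the 7 were already lower in aerial than in attached mycelium (−6.34 to −0.59 over all 7). They had less room to fall there, so the lack of lower calls does not show a lack of response. All 7 were lower in hyphal knots than in attached mycelium of the same age (−7.40 to −3.25), and 0 were called in water-agar knots. The difference between compartments called 3 of them at 1 h and 1 at 24 h. The gene models do not overlap one another, and the first 6 form the longest run of higher neighbours in attached mycelium at 24 h and of lower ones in knots, where shuffled calls gave at most 5.

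The genes raised or lowered in most stresses also moved outside the stresses. Of the 281 higher ones, 107 were higher and 51 lower after 24 h on water agar, and 87 higher and 16 lower at 7.5 h after knots on water agar. The other way, 75 were lower and 25 higher in 6 h primordia than in knots, and 51 lower and 13 higher in 24 h than in 6 h primordia. Of the 200 lower ones, 79 fell and 0 rose in attached mycelium after 1 h of light, 93 fell and 6 rose after 2 h, and 87 were lower and 16 higher in aerial than in attached mycelium in the dark. In germinating oidia they went the other way, with 93 of 181 higher and 25 lower. These are counts of called genes with no test of their own, and the 60 h control libraries of water agar are also a control of the stresses.

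Mycelium overgrown by Trichoderma held 3016 called genes in the shallowest libraries of the series. Low depth is excluded as the whole source. With the repeat models left out and the control thinned to the remaining overgrown counts, 1199 genes were called, and 1073 of the 3016 kept their call and 0 reversed. For the others depth stays open, since thinning also removes power. Reads of Trichoderma counted on conserved genes stay open for the higher genes. Of the 1377 higher genes tested 413 were also higher in at least 3 of 6 control sets without Trichoderma, against 147 for independent lists. Genes that are easily called in any comparison would share lists too, so this excess cannot decide it. For the lower genes foreign reads and a real fall cannot be told apart. Such reads lower no gene, and 219 genes lay at least 4-fold under the median ratio in all 3 overgrown libraries, but only 47 of these had 50 CPM or more in the control, and scarce genes reach 0 by depth alone. Foreign reads that outnumber the fungus' own at most genes would also raise the median ratio itself. Shared reads stay open. The median share of values not whole differed by −0.0536 percentage points (14.9% in both higher and uncalled genes). That share was counted over the libraries of the whole series, so it cannot show sharing within the overgrown ones. In the overgrown libraries 57.8%, 43.2% and 47.3% of nonzero values were not whole, against 18.0%, 19.8% and 18.5% in the control. A response of dying mycelium may remain, as a hypothesis that was not tested.

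Hyphal knots after light and on water agar changed 310 genes in opposite directions. The knots after light were measured against attached mycelium 24 h after light, and a change of that reference may account for the pattern. Against dark attached mycelium the correlation with water-agar knots was 0.22 across genes, with 272 genes called the same way and 58 opposite, and attached mycelium at 24 h itself correlated with water-agar knots at 0.40 (464 the same way, 37 opposite). A single library is excluded, since without knot library 2 the opposite calls numbered 279 against 105 the same way. Without each of the 12 libraries of both kinds of knots and their references in turn they outnumbered the same calls, most narrowly with 250 against 87 without knot library 3 after light. The genes called in the starvation response are argued against as the only source. Over the 6938 genes not called at 2, 8 or 24 h on water agar the correlation was −0.224, with 80 opposite and 34 same calls. Over all genes it was −0.202. Genes under the threshold can carry the starvation response too, so its weaker changes and a wider pattern cannot be told apart.

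For each of the 44 comparisons, 6 libraries make 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave a count as large. The counts that follow come from fits of the compared groups alone. The highest other split called 0 genes, except 1 at pH 4 and 8 in hypoxia. The real splits called 5612 genes in oidia at 18 h, 4556 and 6876 in basidiospores at 4 and 12 h, 6810 between resting oidia and basidiospores, 1373 and 1810 in dark mycelium at 60 and 132 h, and 2165 between aerial and attached mycelium. In aerial mycelium they called 1739 after 1 h and 2078 after 2 h of light, 1481 at 6 h and 203 at 24 h after it, and in attached mycelium 1719, 2453, 1164 and 1845. Knots gave 1546 against attached and 1726 against aerial mycelium, primordia 1418 at 6 h and 1799 at 24 h. The stresses gave 1881 for freezing, 6188 for heat, 1141 for carbon dioxide, 4042 for sclerotia, 1913 for drought, 1575 for cold, 3110 for cutting, 627 for cobalt, 2620 for peroxide, 322 at pH 4, 310 at pH 9, 1827 for sorbitol, 758 for congo red, 115 for hypoxia, 1426 for calcium, 96 for copper, 345 for voriconazole, 3016 for overgrowth and 1434 for first contact. Water agar gave 1566, 2673 and 2844 at 2, 8 and 24 h, and the knot series on water agar 518 at 15 h before, 1093 at the knots and 2543 after.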
